A study of Homo sapiens with 24 samples.

How the data were processed

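RNA from MCF-7 cells, an estrogen receptor positive human breast cancer line, was measured on 24 Affymetrix Human Gene 1.0 ST arrays, 1 array per sample. Per the labels' protocols, cells were transfected with control siRNA (siCtrl) or siRNA against the corepressor SMRT (siSMRT) using oligofectamine in Opti-MEM, then held in phenol red-free medium with 10% charcoal-stripped serum. After 48 h they received vehicle (0.1% ethanol) or 1 nM estradiol (E2) for 4 h or 24 h, RNA was isolated with an RNeasy kit, and fragmented cDNA was labelled with biotin. The labels give 8 groups of 3 experimental replicates and do not say whether the replicates were separate cultures, so p-values below measure the spread between these samples only.

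The deposited table holds 1 intensity per transcript cluster and array on a linear scale, made by the authors with GCOS and RMA, per the submitters' processing notes, which give no versions, genome build or annotation. RMA corrects background, normalizes between arrays and summarises the probes of a cluster. The values themselves show that the 2 times were not processed alike. On the log2 scale, 100% of the 4 h values were whole hundredths (within 0.001 of a hundredth), against at most 0.252% on a 24 h array. Array medians lay between 5.99 and 6.07 at 4 h and between 6.19 and 6.28 at 24 h. A comparison of one time with the other therefore cannot be told apart from the processing, whereas comparisons within a time are not affected by a shift common to that time.

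The deposited intensities were taken to log2 with no further normalization. Of 33297 clusters, 19460 have exactly 1 gene symbol in the platform annotation, 1754 have several and 12083 are not listed there. Symbols were updated through Entrez gene IDs to the RefSeq gene table of assembly GRCh38.p14, used for names only; 19429 matched and the others kept the symbol of the annotation. No coordinates are given, since the files name no build. Clusters with 1 symbol gave 18417 genes; for 769 genes with more than 1 cluster, the cluster with the highest mean over the 24 arrays was used. No file was left out, and no pair of arrays held identical values (highest Pearson r 0.996 over all clusters).

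Gene by gene, a linear model with 1 mean per group was fitted over all 24 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes), leaving 16 residual degrees of freedom plus 5.74 from the prior. Every adjusted p is limma's moderated test with Benjamini-Hochberg adjustment over the 18417 genes of that comparison, two-sided, and a gene passed with an adjusted p under 0.05. The 13 comparisons were E2 against vehicle and siSMRT against siCtrl within each condition, the difference of the E2 effect between siRNAs at each time (E2 by siRNA), the difference of the E2 effect in siCtrl and of the siSMRT effect in vehicle between times, and time in siCtrl vehicle cells. The median standard error of a log2 fold change was 0.09, or 0.13 for differences of effects, and the number of arrays limits the precision. These comparisons, the gene lists and the rule for naming genes were fixed before the data were examined.

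There were 23 fixed gene lists with 479 entries, of which 435 were measured as a gene here and 44 were not. Each list was tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 23 lists of a comparison, and again with the correlation estimated from the arrays. Members were also counted with their p adjusted over the list alone. The genes named are, among genes past the threshold whose 2 groups of arrays do not overlap, those with the highest and lowest fold changes (8 each way for the E2 effect in siCtrl and the siSMRT effect in vehicle, 4 for the other effects within a time, 5 for E2 by siRNA, 3 for differences between times). Up to 4 passing and 2 other members of each list were named too, and ESR1, TFF1, GREB1, PGR, CXCL12, MYC and CCND1 always. NCOR2, the gene of SMRT, and its relative NCOR1 are also on that rule but are named for no cluster, alone or with other symbols, in the annotation used here, so the depletion of SMRT was not analysed here.

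Replicate numbers are shared by all groups. Deviations of same-numbered vehicle and E2 arrays from their group means correlated in the siSMRT arm at 4 h (r 0.38, 0.22 and 0.54 for the 3 numbers) and at 24 h (r 0.53, 0.15 and 0.38), so the numbers pair these arrays, from the data and not from the labels. For the other 6 comparisons of 2 groups within a time at least 1 of the 3 correlations was under 0.1. The alternatives were all clusters in place of named genes, a filter on dim genes (mean under the 30th percentile), quantile normalization over the 24 arrays, median centring, a trended and robust prior, array weights, only the groups compared, a 1.5-fold minimum, replicate blocks and leaving out each array. A fit on the 12 arrays of a time, the replicate block within siRNA and time (also for the lists), and left-out arrays for the shared E2 response and the gene lists were chosen after seeing the data.

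The steps were tested on simulated data with 200 changed genes added to noise of the size seen in these arrays. That noise was drawn independently for each gene and array, whereas same-numbered siSMRT arrays deviate together. The numbers below therefore need not hold for the real arrays. In the simulated siSMRT comparison in vehicle at 4 h, over 18417 genes, 13 of 50 genes changed 1.25-fold, 45 of 50 changed 1.5-fold and 50 of 50 changed 2-fold were recovered, with 8 false calls. For E2 in siCtrl at 24 h the numbers were 22, 45 and 50 of 50, with 11 false calls, and for E2 by siRNA at 24 h 3, 29 and 47 of 50, with 7 false calls.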

Results

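The series asked which genes depend on SMRT, the product of NCOR2 and a corepressor of nuclear receptors, in MCF-7 cells with and without estradiol (E2). Gene expression was measured on 24 arrays in 8 groups of 3: control siRNA (siCtrl) or SMRT siRNA (siSMRT), vehicle or 1 nM E2, for 4 h or 24 h. The mean intensity of an array lay between 353.07 and 379.69, and array medians within a time differed by less than 0.1 on the log2 scale. NCOR2 is named for no cluster in the annotation used here, which leaves 12083 clusters unlisted, so the depletion itself was not analysed.

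E2 for 4 h in control cells raised most of the estrogen-induced genes measured. GREB1, an estrogen receptor target and coactivator (cluster 8040292), stood at a log2 level of 8.06 ± 0.25 with vehicle and 10.51 ± 0.08 with E2 (SD, n = 3). Its log2 fold change was 2.45 (SE 0.18, adjusted p = 7.2e-09). PGR, the progesterone receptor (cluster 7951165), rose by 1.98 and CXCL12, a chemokine (cluster 7933194), by 1.70. RAPGEFL1 (1.98), IGFBP4 (1.83), MYBL1 (1.68), RBM24 (1.65) and ASB13 (1.58) rose as well. CYP1A1, a cytochrome P450 controlled by the aryl hydrocarbon receptor, changed by −3.10 (SE 0.21, adjusted p = 1.8e-09). TRERF1 (−1.29), RNF43 (−1.22), an inhibitor of Wnt receptors, ST8SIA4 (−1.21), HCAR1 (−1.15), DRD1 (−1.15), BMF (−1.08) and RNF144B (−1.07) were lower. In all, 738 genes were higher and 624 lower, 175 and 81 of them by at least 1.5-fold.

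Of 30 estrogen-induced genes measured, 27 rose after 4 h of E2, 0 fell and 3 did not pass. Of the same genes, 28 passed adjusted over the list alone. The list's median log2 fold change was 0.91 (camera adjusted p = 1.75e-49; adjusted p = 5.45e-05 with an estimated correlation). MYC rose by 1.20 (adjusted p = 3e-11) and CCND1, cyclin D1, by 0.67 (adjusted p = 3e-05). TFF1, a secreted trefoil factor, had a log2 fold change of 0.26 (adjusted p = 0.37). Of 12 estrogen-repressed genes, 7 fell and 1 rose (median −0.47, camera adjusted p = 2.35e-11, adjusted p = 0.0108 with an estimated correlation). CCNG2 (−0.91), ENC1 (−0.92) and TP53INP1 (−1.06) were among those lower, and 9 fell and 1 rose adjusted over the list alone. ESR1, the gene of estrogen receptor alpha, had a log2 fold change of −0.26 (adjusted p = 0.056), which passed in 7 alternatives and without siCtrl_Veh_4h replicate 1 (adjusted p = 0.024).

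Ribosome biogenesis genes rose together with 4 h of E2, 16 of 21 being higher and 0 lower (19 adjusted over the list alone). NOP16 rose by 0.88, NOP2 by 0.59, RRP12 by 0.58 and WDR43 by 0.57 (list median 0.47, camera adjusted p = 3.94e-23, adjusted p = 0.0114 with an estimated correlation). Immediate early genes went both ways, with 5 higher and 2 lower of 16 (6 and 2 adjusted over the list alone). FOS rose by 1.38, EGR3 by 1.01 and FOSL2 by 0.71. Their camera adjusted p was 0.00229, and adjusted p = 0.206 with an estimated correlation. Mitosis genes had a median of −0.15 with 0 of 43 passing (camera adjusted p = 0.000377, adjusted p = 0.734 with an estimated correlation), and DNA replication genes 0 of 40 (camera adjusted p = 0.799). Centring each array on its median turned the split of calls to 582 higher and 795 lower. The total of 1362 genes was 894 without siCtrl_Veh_4h replicate 1 and 839 without siCtrl_E2_4h replicate 2.

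**Figure D1:**
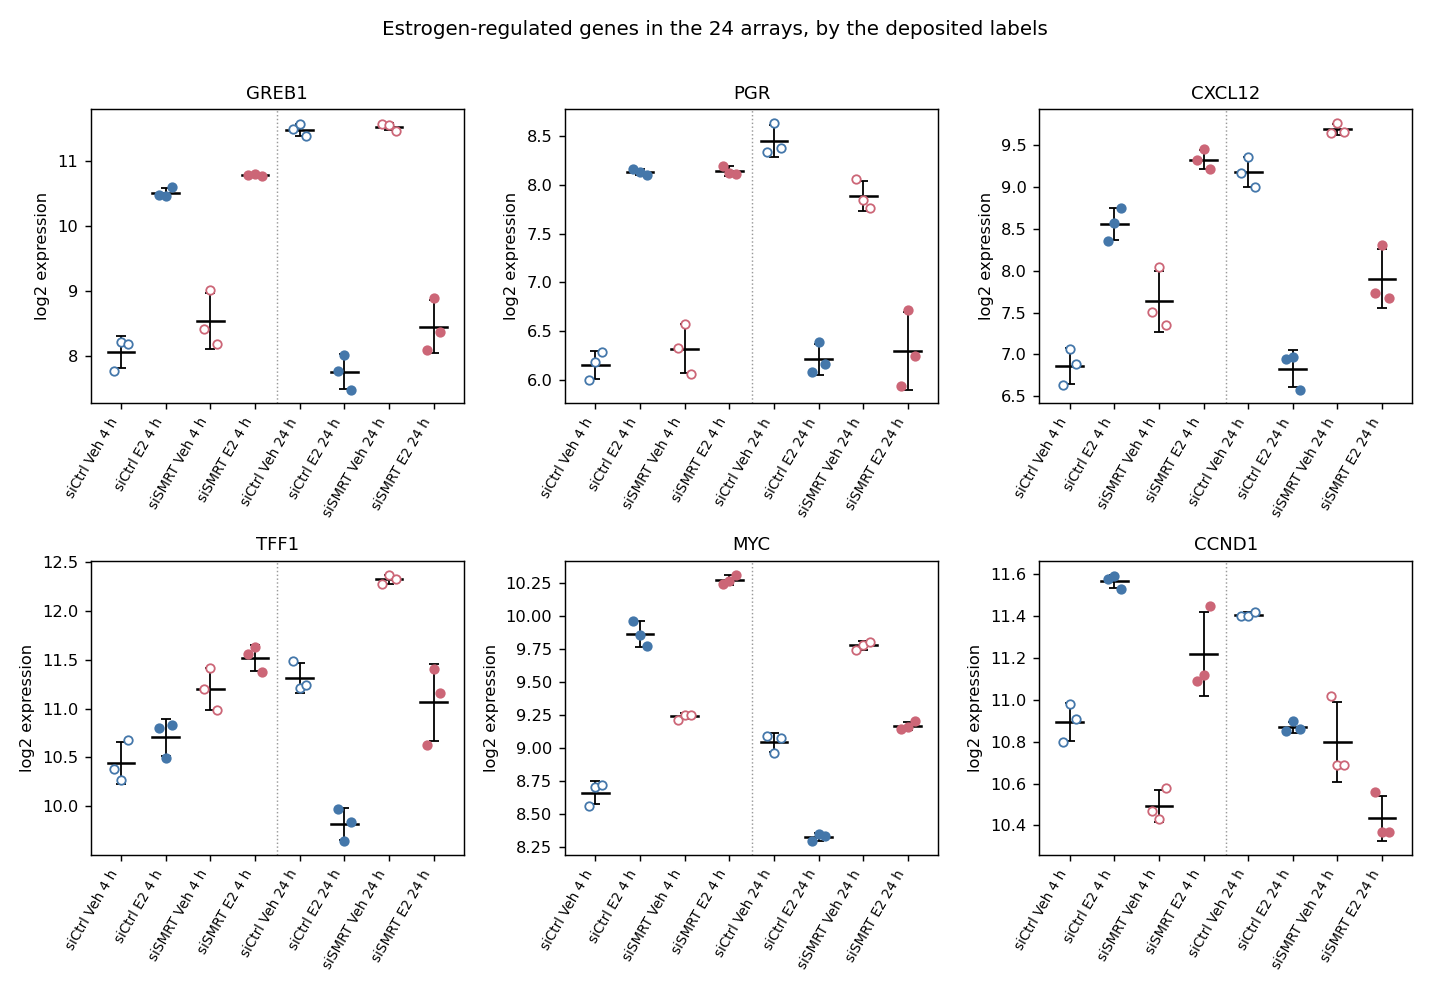
Log2 expression of 6 estrogen-regulated genes in each of the 24 arrays by the deposited labels (blue siCtrl, red siSMRT, open vehicle, filled E2; lines are means and bars SD, n = 3). GREB1, PGR and CXCL12 are higher with E2 at 4 h and lower in the arrays labelled E2 at 24 h.

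After 24 h the same genes stood the other way round. In control cells GREB1 was at 11.48 ± 0.09 in the arrays labelled vehicle and 7.76 ± 0.27 in those labelled E2 (SD, n = 3). The log2 fold change was −3.71 (SE 0.18, adjusted p = 3.8e-12). PGR (−2.24), CXCL12 (−2.35), MGP (−2.41), RBM24 (−2.21), MYBL1 (−2.19), RAPGEFL1 (−2.17), CDH26 (−2.17), TFF1 (−1.49), MYC (−0.72) and CCND1 (−0.54) were all lower in the arrays labelled E2. IL1R1, the interleukin 1 receptor, was higher by 2.42, with KCNJ13 (1.89), ST8SIA4 (1.85), TP53INP1 (1.79), ELF5 (1.78), VTCN1 (1.78), RNF144B (1.74) and LIPH (1.63). These directions are drawn from the labels as deposited. The 4 h response runs against the 24 h labels, so for 24 h the groups are called the arrays labelled vehicle and the arrays labelled E2 throughout. In all, 1884 genes were higher and 1386 lower in the arrays labelled E2, 318 and 189 of them by at least 1.5-fold.

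Of the 30 estrogen-induced genes, 28 were lower in the siCtrl arrays labelled E2 at 24 h and 0 higher (30 lower adjusted over the list alone; median −0.92, camera adjusted p = 9.43e-40, adjusted p = 0.000208 with an estimated correlation). Of the 12 estrogen-repressed genes, 10 were higher and 1 lower (11 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 2.09e-12, adjusted p = 0.00755 with an estimated correlation), including BLNK (1.14), PNRC1 (0.95) and ERBB2 (0.68). Ribosome biogenesis genes were lower in 17 of 21 cases with 0 higher (20 lower adjusted over the list alone), RRS1 being at −0.70. Their median was −0.39 (camera adjusted p = 9.46e-13, adjusted p = 0.1 with an estimated correlation). Mitosis genes were lower in 23 of 43 cases with 0 higher (38 adjusted over the list alone; median −0.44, camera adjusted p = 1.95e-13, adjusted p = 0.405 with an estimated correlation). DNA replication genes were lower in 13 of 40 cases with 0 higher (14 adjusted over the list alone; median −0.27, camera adjusted p = 4.59e-07, adjusted p = 0.432 with an estimated correlation). PLK1 (−0.57), CDCA8 (−0.59), TOP2A (−0.52) and CDC6 (−0.55) were lower. Among anti-apoptotic genes 5 of 10 were higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0428, adjusted p = 0.101 with an estimated correlation). The camera adjusted p of that list reached 0.0602 without siCtrl_E2_24h replicate 2 and also passed 0.05 without siCtrl_Veh_24h replicate 2. ESR1 was higher by 0.24 (adjusted p = 0.04). Its call was lost without 5 of the 6 arrays (adjusted p 0.061 to 0.13; kept without siCtrl_E2_24h replicate 3). With median centring the split of all calls was 2352 higher and 917 lower.

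The difference of the E2 effect between times in control cells was tested directly. This difference is wider than a change of sign, as it also takes in genes that responded at a single time or by unequal amounts. It passed for 4097 genes, 2238 with a higher and 1859 with a lower log2 fold change at 24 h than at 4 h (2961 and 1177 with median centring). GREB1 differed by −6.16 (SE 0.26, adjusted p = 2.3e-13), PGR by −4.22, RAPGEFL1 by −4.14 and CXCL12 by −4.05, and on the other side CYP1A1 by 3.74, IL1R1 by 3.34 and ST8SIA4 by 3.06. Of the genes that rose at 4 h, 409 were lower in the arrays labelled E2 at 24 h (55.5 by chance for independent lists) and 6 higher (75.5 by chance). Of those that fell, 423 were higher (63.8 by chance) and 1 lower (47 by chance). Across all genes, which are not independent replicates, the fold changes at the 2 times correlated at Pearson r = −0.62 (Spearman −0.51). Estrogen-induced genes were lower in 29 of 30 cases in this difference (29 adjusted over the list alone; camera adjusted p = 1.92e-43, adjusted p = 0.000122 with an estimated correlation). Estrogen-repressed genes were higher in 10 and lower in 1 of 12 (11 and 1 adjusted over the list alone; camera adjusted p = 1.35e-12, adjusted p = 0.00671 with an estimated correlation).

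**Figure D2:**
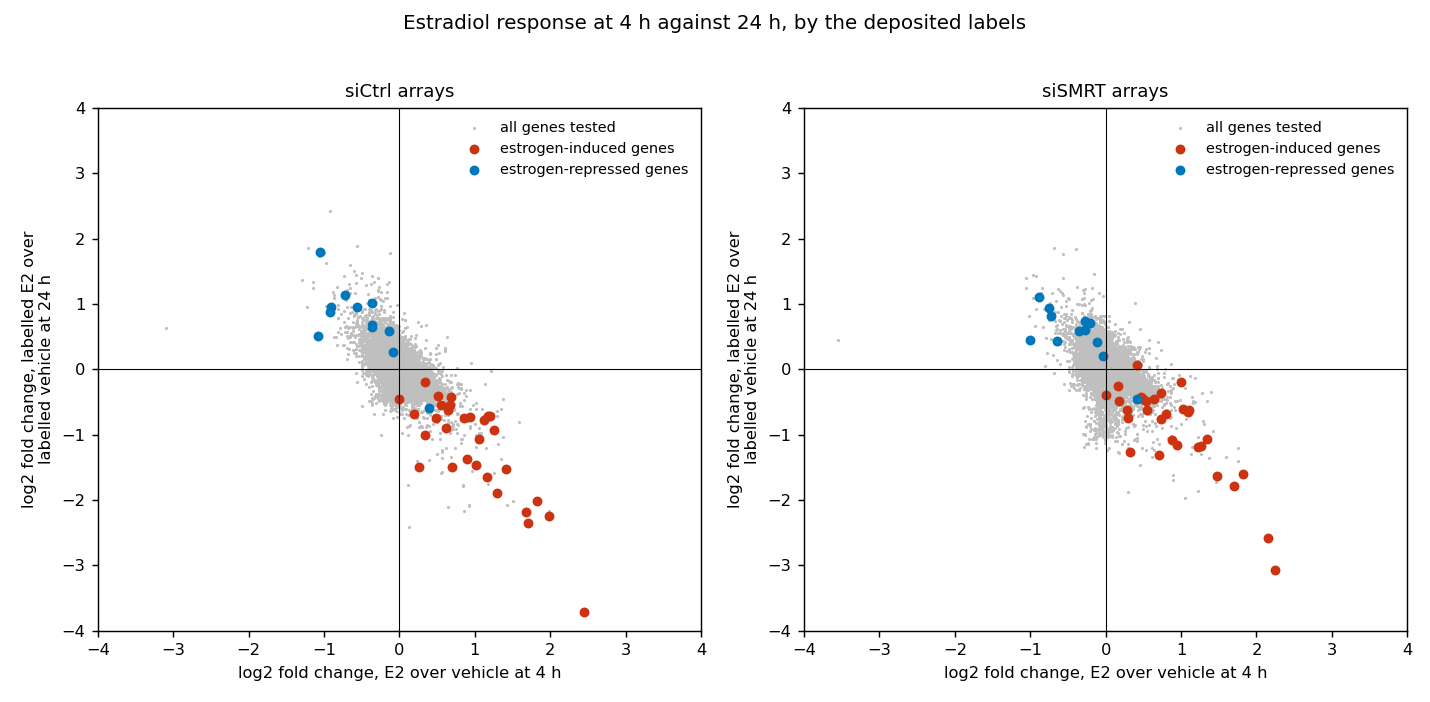
Log2 fold change of E2 over vehicle at 4 h (x axis) against the arrays labelled E2 over those labelled vehicle at 24 h (y axis) for 18417 genes, in siCtrl (left) and siSMRT arrays (right). Estrogen-induced genes (red) lie mostly at the lower right and estrogen-repressed genes (blue) at the upper left; r across genes is −0.62 and −0.45.

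Control cells labelled vehicle also differed between times in the estrogen genes. GREB1 was higher by 3.41 at 24 h than at 4 h (SE 0.18, adjusted p = 2.7e-11), CXCL12 by 2.32 and PGR by 2.30, while CYP1A1 (−4.86), ST8SIA4 (−2.02) and LXN (−1.93) were lower. Estrogen-induced genes were higher in 27 of 30 cases with 0 lower, adjusted over all genes and over the list alone (median 0.89, camera adjusted p = 2.19e-11, adjusted p = 0.0351 with an estimated correlation). Processing differed between times, and the median of all 18417 genes was 0.14. The split of 7275 higher and 2530 lower became 4052 and 3644 with quantile normalization (median 0.02) and 2803 and 6837 with median centring (median −0.11).

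In vehicle-treated cells at 4 h, interferon-stimulated genes were higher and replication and mitosis genes lower with siSMRT than with siCtrl. MX2, an antiviral GTPase, was higher by 2.36 (SE 0.72, adjusted p = 0.039), OAS2 by 1.77, APOL1 by 1.54, IFIT2 by 1.42 and IFIT3 by 1.34. ALCAM, a cell adhesion molecule, rose by 1.19 (SE 0.12, adjusted p = 3.4e-06), CHPF, a chondroitin polymerizing factor, by 1.20 (adjusted p = 2.8e-06) and PLA2G10 by 1.24. PBK, a mitotic kinase, fell by 1.49 (SE 0.26, adjusted p = 0.00086). RAD51AP1 (−1.17), CENPW (−1.07), E2F7 (−1.06), DTL (−1.05), WEE1 (−0.94), SHCBP1 (−0.94) and CENPI (−0.94) were lower as well. In all, 718 genes were higher and 1096 lower, 97 and 201 of them by at least 1.5-fold. Calls of the 5 interferon-stimulated genes named were lost without siCtrl_Veh_4h replicate 1 or 2 or siSMRT_Veh_4h replicate 1 or 2 (adjusted p 0.057 to 0.23). That of PLA2G10 was lost without siCtrl_Veh_4h replicate 3 or siSMRT_Veh_4h replicate 1 (0.051 and 0.056).

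Of 32 interferon-stimulated genes measured, 17 were higher and 0 lower with siSMRT in vehicle at 4 h, and 24 were higher adjusted over the list alone. The median was 0.83 (camera adjusted p = 4.16e-12, adjusted p = 0.232 with an estimated correlation). The mean of the list varied widely between replicates: 9.02 ± 0.34 in siCtrl and 9.83 ± 0.37 in siSMRT (SD, n = 3). Replicate 2 had the lowest mean in each of the 4 siCtrl groups (8.63 and 8.32 at 4 h, 8.59 and 8.58 at 24 h). DNA replication genes fell in 35 of 40 cases and mitosis genes in 38 of 43, with 0 higher in either list (39 and 40 lower adjusted over the list alone). Their medians were −0.55 and −0.63 (camera adjusted p = 6.97e-33 and 1.47e-33). With an estimated correlation both had an adjusted p = 0.0908. FOXM1, a transcription factor of the G2/M genes, fell by 0.70 (adjusted p = 3e-05), GINS1 by 0.78, PRIM1 by 0.69, POLA1 by 0.66 and AURKA by 0.56.

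Estrogen-regulated genes moved unevenly with siSMRT in vehicle at 4 h. TFF1 stood at 10.44 ± 0.21 in siCtrl and 11.20 ± 0.22 in siSMRT (SD, n = 3), a log2 fold change of 0.75 (adjusted p = 0.003). CXCL12 was higher by 0.78, IGFBP4 by 0.69, MYC by 0.58 (adjusted p = 3.4e-06) and XBP1 by 0.52. Lower were CCND1 (−0.40, adjusted p = 0.0063) and MYBL1 (−0.77). GREB1 (0.48, adjusted p = 0.097; 0.026 without siSMRT_Veh_4h replicate 3), PGR (0.17, adjusted p = 0.53) and ESR1 (0.18, adjusted p = 0.17) did not pass. Over the estrogen-induced list 9 of 30 were higher and 2 lower (13 and 2 adjusted over the list alone; median 0.22, camera adjusted p = 0.000346, adjusted p = 0.206 with an estimated correlation). Of 12 estrogen-repressed genes 1 was higher and 1 lower (camera adjusted p = 0.534). Among 11 estrogen receptor coactivators CARM1 was higher by 0.23 and NCOA2 lower at −0.57 (camera adjusted p = 0.738). Of the NCoR and SMRT complex list 4 members were measured and none passed in limma (camera adjusted p = 0.431).

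Stress and signalling lists were higher by smaller amounts in the same comparison. Unfolded protein response and ATF4 targets were higher in 5 of 20 cases (7 adjusted over the list alone; median 0.20), with ATF4 at 0.34. Immediate early genes were higher in 3 of 16 (8 adjusted over the list alone; 0.22), with IER3 at 0.60, and p53 targets in 7 of 24 (8 higher and 2 lower adjusted over the list alone; 0.13). None of these 3 lists had a lower gene adjusted over all genes. Pro-apoptotic genes went both ways (7 higher, 3 lower of 26; 8 and 3 adjusted over the list alone), with BAK1 at 0.48. Hypoxia and glycolysis genes were higher in 4 of 17 (5 adjusted over the list alone), with HK2 at 0.83 and VEGFA at 0.47. Luminal epithelial markers were higher in 2 of 15 cases (7 adjusted over the list alone), Notch pathway targets in 2 of 12, with JAG1 at 0.37. Cholesterol synthesis genes were lower in 4 of 16 (7 adjusted over the list alone), with MVK at −0.34. Their camera adjusted p ranged from 2.35e-05 for cholesterol synthesis to 0.0238 for pro-apoptotic genes. With an estimated correlation none of these lists passed (adjusted p = 0.0908 for immediate early, Notch and cholesterol genes, 0.232 for ATF4 targets).

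Several lists did not pass camera with siSMRT in vehicle at 4 h. They were NF-kappaB and inflammatory genes (1 of 20 higher, adjusted p = 0.349) and retinoic acid receptor targets (0 of 11, adjusted p = 0.494). Neither did cell cycle inhibitors (1 higher and 3 lower of 15, adjusted p = 0.767), anti-apoptotic genes (1 and 1 of 10, adjusted p = 0.993) and ribosome biogenesis genes (3 of 21 higher, adjusted p = 0.0963). Markers of other cell types did not pass either: basal epithelial 0 of 7 (adjusted p = 0.21), fibroblast and mesenchymal 1 of 18 (adjusted p = 0.0748) and leukocyte 0 of 15 (adjusted p = 0.743). Over all genes the split became 497 higher and 1332 lower with median centring. The total of 1814 genes fell to 1190 and 970 without siCtrl_Veh_4h replicate 1 and 2, and to 944 and 1083 without siSMRT_Veh_4h replicate 1 and 2.

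In the arrays labelled vehicle at 24 h interferon-stimulated genes were again higher with siSMRT. MX2 was higher by 3.62 (SE 0.72, adjusted p = 0.0022), OAS2 by 2.76, IFIT2 by 2.69, RSAD2 by 2.39, APOL1 by 2.32, SAMD9L by 2.25 and LAMP3 by 2.02. PLEKHS1 was higher by 2.10 (SE 0.18, adjusted p = 1.6e-07). TNFSF10, the death ligand TRAIL, was higher by 1.92. FRRS1 (−1.15), GJA1, the gap junction protein connexin 43 (−1.08, SE 0.10, adjusted p = 4.8e-07), TMT1A (−1.05), LAMB1 (−0.99), SEMA6A (−0.98), PBK (−0.98), SDK2 (−0.93) and RAD51AP1 (−0.89) were lower. In all, 1013 genes were higher and 799 lower, 264 and 52 of them by at least 1.5-fold. Without siSMRT_Veh_24h replicate 3 the adjusted p was 0.069 for RSAD2, 0.16 for SAMD9L, 0.097 for LAMP3 and 0.09 for PBK. All 4 calls were also lost without siCtrl_Veh_24h replicate 2 (0.051 to 0.075), and those of SAMD9L, LAMP3 and PBK without siSMRT_Veh_24h replicate 2 (0.07 to 0.12). SAMD9L was lost without siCtrl_Veh_24h replicate 1 (0.066) or 3 (0.071) and PBK without siCtrl_Veh_24h replicate 3 (0.067).

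Of the 32 interferon-stimulated genes, 28 were higher and 0 lower with siSMRT in the arrays labelled vehicle at 24 h (32 adjusted over the list alone). OASL (1.89), IFIH1 (1.82) and RIGI (1.70) were among them, and the median was 1.27 (camera adjusted p = 4.87e-31, adjusted p = 0.0605 with an estimated correlation). Immediate early genes were higher in 10 of 16 cases with 0 lower (12 adjusted over the list alone; median 0.34), with JUN at 0.61 and JUNB at 0.45. Hypoxia and glycolysis genes were higher in 6 of 17 (7 adjusted over the list alone), with HK2 at 0.73, p53 targets in 6 of 24 (8 adjusted over the list alone), with TP53INP1 at 0.99. Pro-apoptotic genes were higher in 9 of 26 with 1 lower (10 and 1 adjusted over the list alone), with BCL2L11 at 0.60, and luminal epithelial markers in 5 of 15 (6 adjusted over the list alone), with SPDEF at 0.56. These 5 lists passed camera (adjusted p between 8.29e-08 and 0.00048) and passed with an estimated correlation too (adjusted p between 0.0293 and 0.0491). ATF4 targets were higher in 7 of 20 cases (15 adjusted over the list alone), with DDIT4 at 1.16 and DDIT3 at 0.82 (camera adjusted p = 1.42e-09, adjusted p = 0.0821 with an estimated correlation).

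Of the DNA replication and mitosis genes, 6 of 40 and 5 of 43 were lower and 0 higher in the arrays labelled vehicle at 24 h (11 and 16 adjusted over the list alone). FOXM1 was at −0.42 and TK1 at −0.49. The list medians were −0.21 and −0.25 (camera adjusted p = 2.24e-05 and 6.03e-07, adjusted p = 0.468 and 0.431 with an estimated correlation). TFF1 was higher by 1.01 (adjusted p = 0.00019) and MYC by 0.73 (adjusted p = 9.3e-08), and CCND1 lower at −0.61 (adjusted p = 0.00017). PGR was lower at −0.56 (adjusted p = 0.017), a call lost without siCtrl_Veh_24h replicate 2 or siSMRT_Veh_24h replicate 2 or 3 (adjusted p 0.062 to 0.088). CXCL12 (0.51, adjusted p = 0.059), GREB1 (0.05, adjusted p = 0.9) and ESR1 (0.07, adjusted p = 0.68) did not pass. The estrogen-induced list had 5 higher and 6 lower of 30 (7 and 8 adjusted over the list alone; camera adjusted p = 0.576). Estrogen-repressed genes were higher in 4 of 12 cases (6 adjusted over the list alone; camera adjusted p = 8.45e-06, adjusted p = 0.0552 with an estimated correlation). With median centring the split of all calls was 1117 higher and 544 lower. The total of 1812 genes was 1138 and 1086 without siSMRT_Veh_24h replicate 2 and 3.

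**Figure D3:**
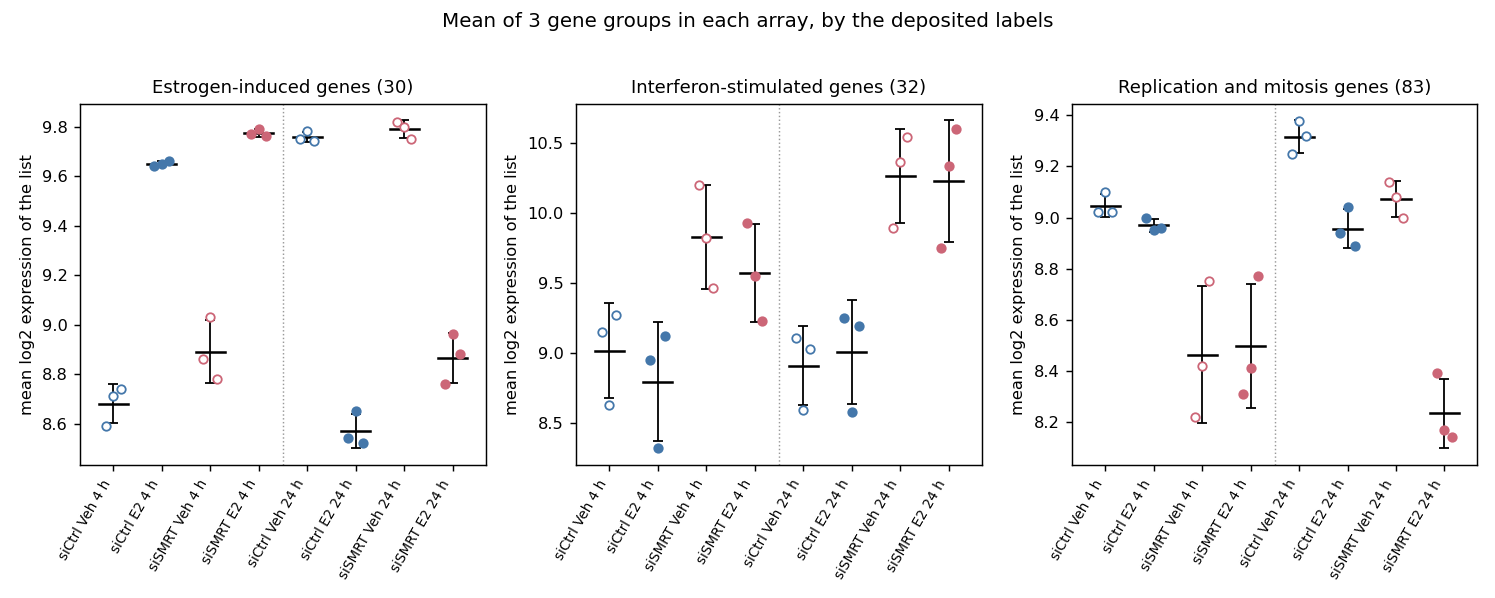
Mean log2 expression of the estrogen-induced (30), interferon-stimulated (32) and replication and mitosis genes (83) in each array by the deposited labels (blue siCtrl, red siSMRT, open vehicle, filled E2; lines are means and bars SD, n = 3). The interferon-stimulated mean is 8.80 to 9.02 in the 4 siCtrl groups and 9.57 to 10.26 in the 4 siSMRT groups.

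With E2 at 4 h, interferon-stimulated genes were again higher and replication and mitosis genes lower with siSMRT. ALCAM rose by 1.56 (SE 0.12, adjusted p = 1.1e-07), PLEKHS1 by 1.21, LGALS9, a galectin, by 1.62 and MX2 by 2.37 (SE 0.72, adjusted p = 0.05). PBK (−1.24), RAD51AP1 (−1.12), CYP1A1 (−1.04, adjusted p = 0.0041) and SESN3 (−0.98) were lower. Interferon-stimulated genes were higher in 9 of 32 cases with 0 lower (23 adjusted over the list alone; median 0.75, camera adjusted p = 9.99e-15, adjusted p = 0.184 with an estimated correlation). Their median was 0.48 without siCtrl_E2_4h replicate 2. DNA replication genes fell in 24 of 40 cases and mitosis genes in 33 of 43 with 0 higher (35 and 39 adjusted over the list alone), with FOXM1 at −0.68 and BIRC5, survivin, at −0.71. The medians were −0.42 and −0.54 (camera adjusted p = 6.76e-25 and 6.71e-33, adjusted p = 0.135 for both with an estimated correlation). TFF1 was higher by 0.81, CXCL12 by 0.77 and MYC by 0.41, and CCND1 was lower at −0.35 (adjusted p = 0.024). GREB1 (0.27, adjusted p = 0.47), PGR (0.01, adjusted p = 0.98) and ESR1 (0.20, adjusted p = 0.16) did not pass. In all, 632 genes were higher and 573 lower, 89 and 90 of them by at least 1.5-fold. The total of 1205 was 768 and 620 without siCtrl_E2_4h replicate 1 and 2, and 564 and 595 without siSMRT_E2_4h replicate 1 and 2. Leaving out any of these 4 arrays also ended the call of CCND1 (adjusted p 0.072 to 0.15). The call of MX2 was lost without any of these 4 or siCtrl_E2_4h replicate 3 (0.064 to 0.26) and that of LGALS9 without siCtrl_E2_4h replicate 2 (0.053) or siSMRT_E2_4h replicate 2 (0.05).

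In the arrays labelled E2 at 24 h, interferon-stimulated genes were higher and replication and mitosis genes lower with siSMRT as well. MX2 was higher by 3.47 (SE 0.72, adjusted p = 0.0019), OAS2 by 2.48, RSAD2 by 2.39 and APOL1 by 2.25. PBK fell by 1.65 (SE 0.26, adjusted p = 0.00018) and ZNF730 by 1.36, and KCNJ13, a potassium channel (adjusted p = 1.6e-07), and E2F7 were lower as well. Interferon-stimulated genes were higher in 27 of 32 cases with 0 lower (30 adjusted over the list alone; median 1.11, camera adjusted p = 1.36e-23, adjusted p = 0.11 with an estimated correlation). DNA replication genes fell in 38 of 40 cases and mitosis genes in 40 of 43 with 0 higher (39 and 41 adjusted over the list alone). FOXM1 was at −0.88, GINS1 at −0.82, PLK1 at −0.71 and BIRC5 at −0.94. The medians of the lists were −0.65 and −0.79 (camera adjusted p = 7.37e-39 and 2.94e-39, adjusted p = 0.0732 for both with an estimated correlation). Estrogen-induced genes were higher in 13 of 30 cases and lower in 2 (15 and 2 adjusted over the list alone; median 0.30, camera adjusted p = 2.22e-07, adjusted p = 0.0766 with an estimated correlation). TFF1 was higher by 1.24, CXCL12 by 1.08, MYC by 0.84, IGFBP4 by 0.84 and GREB1 by 0.69 (adjusted p = 0.012; 0.083 without siCtrl_E2_24h replicate 3 and 0.11 without siSMRT_E2_24h replicate 2). CCND1 was lower at −0.43 (adjusted p = 0.0022), and PGR (0.09, adjusted p = 0.81) and ESR1 (0.14, adjusted p = 0.32) did not pass. In all, 1113 genes were higher and 1138 lower, 269 and 259 of them by at least 1.5-fold. The call of RSAD2 was lost without siCtrl_E2_24h replicate 2 (adjusted p = 0.065) and siSMRT_E2_24h replicate 3 (0.07).

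**Figure D4:**
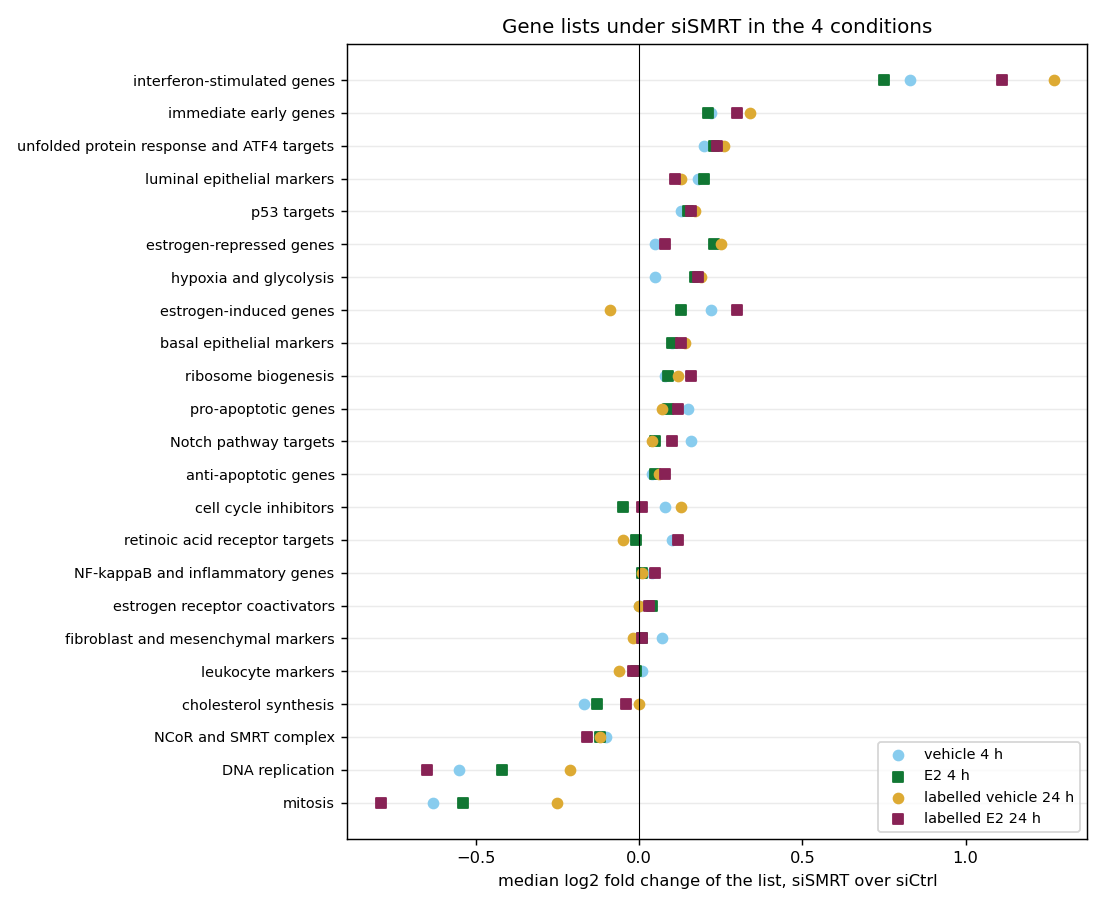
Median log2 fold change of siSMRT over siCtrl for the 23 gene lists (y axis) in the 4 conditions, with 24 h conditions named as labelled. Interferon-stimulated genes have medians of 0.75 to 1.27 and mitosis genes of −0.79 to −0.25.

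The 4 siSMRT comparisons, which share no arrays, resembled each other. Of genes higher in vehicle at 4 h, 388 were higher in the arrays labelled vehicle at 24 h (39.5 by chance for independent lists), and 420 were lower in both (47.5 by chance). Across genes, which are not independent replicates, the correlation of fold changes was r = 0.58 between vehicle at 4 h and labelled vehicle at 24 h, and 0.77 between E2 at 4 h and labelled E2 at 24 h. With the labels crossed it was 0.75 between vehicle at 4 h and labelled E2 at 24 h, and 0.71 between E2 at 4 h and labelled vehicle at 24 h. The difference of the siSMRT effect between times sets vehicle at 4 h against the arrays labelled vehicle at 24 h. Those would be E2 arrays if the labels were exchanged. The difference passed for 4 genes: ST8SIA4 (0.69), and GJA1 (−0.95), SDK2 (−1.04) and PREX1 (−0.65) (SE 0.09 to 0.14). That count, 1 higher and 3 lower, was 9 (3 and 6) without siCtrl_Veh_4h replicate 3, 7 (3 and 4) without siCtrl_Veh_24h replicate 2 and 20 (14 and 6) without siSMRT_Veh_24h replicate 1, and the call of PREX1 was lost without siSMRT_Veh_4h replicate 1 (adjusted p = 0.054).

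E2 also acted on the estrogen genes in siSMRT cells. At 4 h GREB1 rose by 2.24, MYBL1 by 2.15, PGR by 1.82, RBM24 by 1.76 CXCL12 by 1.70, MYC by 1.03 and CCND1 by 0.73. CYP1A1 (−3.55), TRERF1 (−1.06), ST8SIA4 (−1.06) and RNF43 (−1.02) were lower. In all, 815 genes were higher and 334 lower, 184 and 44 of them by at least 1.5-fold. Estrogen-induced genes rose in 24 of 30 cases with 0 lower (27 adjusted over the list alone; median 0.77, camera adjusted p = 2.37e-51, adjusted p = 4.31e-05 with an estimated correlation). Ribosome biogenesis genes rose in 17 of 21 (19 adjusted over the list alone; camera adjusted p = 6.1e-28, adjusted p = 0.00758 with an estimated correlation). At 24 h, in the arrays labelled E2, GREB1 (−3.07), MYBL1 (−2.58), SFXN2 (−1.97) and MGP (−1.87) were lower and IL1R1 (1.86), ITGB6 (1.84), VTCN1 (1.76) and TARP (1.46) higher. By these labels 1700 genes were higher and 1277 lower, 242 and 357 of them by at least 1.5-fold. Estrogen-induced genes were lower in 26 of 30 cases there, mitosis genes in 43 of 43 and DNA replication genes in 39 of 40, with 0 higher (28, 43 and 39 adjusted over the list alone). Their camera adjusted p was 8.61e-34, 5.56e-46 and 8.53e-39, and adjusted p = 0.00058, 0.0484 and 0.0484 with an estimated correlation. With the paired replicate numbers as a block within siRNA and time, the 4 h count rose from 1149 to 1729 genes (1104 higher, 625 lower). None of the 32 interferon-stimulated genes passed at 4 h without the block in limma (median −0.24, camera adjusted p = 0.00962, adjusted p = 0.806 with an estimated correlation). That median ranged from −0.41 without siSMRT_Veh_4h replicate 3 or siSMRT_E2_4h replicate 1 to −0.08 and −0.07 without siSMRT_Veh_4h replicate 1 or siSMRT_E2_4h replicate 3, where the call was lost (adjusted p up to 0.517). Their mean was lower with E2 in 3 of 3 pairs (−0.27, −0.27 and −0.23). With the block 14 were lower and 0 higher (25 lower adjusted over the list alone; camera adjusted p = 2.97e-13, adjusted p = 0.0919 with an estimated correlation). At 24 h by label the siSMRT pairs went both ways (−0.14, −0.03 and 0.06), as did same-numbered siCtrl arrays (0.14, −0.02 and 0.16). In siCtrl at 4 h, where the check did not pair the arrays, the interferon-stimulated mean was lower with E2 in same-numbered arrays too (−0.19, −0.31 and −0.15). There 1 of 32 was lower without the block (camera adjusted p = 0.0222, adjusted p = 0.747 with an estimated correlation), a camera call lost without siCtrl_Veh_4h replicate 1 or 3 or siCtrl_E2_4h replicate 2 (up to 0.888). With the block 13 were lower and 0 higher (camera adjusted p = 5.16e-10, adjusted p = 0.144 with an estimated correlation), and the list's difference between siRNAs did not pass camera (median −0.02, adjusted p = 0.983).

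Genes called in both siRNA arms went the same way, as 500 rose and 244 fell at 4 h (32.7 and 11.3 by chance for independent lists) and 1257 and 731 at 24 h by label (174 and 96.1 by chance), with 0 opposite at either time. The fold changes correlated across genes at r = 0.65 at 4 h and r = 0.79 at 24 h. Tested directly, the E2 effect at 4 h differed between siRNAs for 0 genes in limma (lowest adjusted p 0.482), and for 0 under each alternative run. At an unadjusted p under 0.05 there were 1237 genes, against 921 by chance. The differences for GREB1 (−0.21), PGR (−0.15), CXCL12 (−0.01), TFF1 (0.06), MYC (−0.17), CCND1 (0.06) and ESR1 (0.02) all had an adjusted p of 0.75 or more.

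At 24 h by label the E2 effect differed between siRNAs for 8 genes. KCNJ13 was higher in the arrays labelled E2 in siCtrl (1.89) and differed by −1.51 in siSMRT (SE 0.18, adjusted p = 0.00042). It is a dim gene, at 4.14 and 6.03 in the siCtrl arrays labelled vehicle and E2 and 4.15 and 4.53 in siSMRT, and the filter on dim genes leaves it out. GJA1 (1.09, SE 0.14, adjusted p = 0.00096), SDK2 (1.06), SYTL5 (1.00), RAPGEFL1 (0.96), JAK2, the cytokine receptor kinase (0.95), IGFBP4 (0.93) and PREX1 (0.67) had differences above 0. In siSMRT, GJA1, SDK2, SYTL5, RAPGEFL1, JAK2 and IGFBP4 were lower in the arrays labelled E2 than in those labelled vehicle. For these genes a difference above 0 is therefore a smaller fall than in siCtrl. Replication and mitosis genes were lower in the arrays labelled E2 by more in siSMRT than in siCtrl. None of 40 and 43 passed over all genes, and 30 of each list did adjusted over the list alone (medians −0.46 and −0.53, camera adjusted p = 4.71e-43 and 8.78e-39, adjusted p = 0.067 and 0.103 with an estimated correlation). Estrogen-induced genes had a median difference of 0.26 (1 of 30 passed, 4 adjusted over the list alone; camera adjusted p = 1.56e-10, adjusted p = 0.067 with an estimated correlation). The mean of that list in labelled vehicle and labelled E2 was 9.76 and 8.57 in siCtrl, and 9.79 and 8.87 in siSMRT. The count of genes was 19 (10 higher, 9 lower) without siSMRT_Veh_24h replicate 1 and 177 (36 higher, 141 lower) with replicate numbers as a block within siRNA and time. With only the groups compared 4 genes had a difference above 0 and 5 below, and RAPGEFL1 (adjusted p = 0.088), JAK2 (0.096) and IGFBP4 (0.08) did not pass. The call of JAK2 was also lost without siCtrl_Veh_24h replicate 2, siCtrl_E2_24h replicate 1 or 2, siSMRT_Veh_24h replicate 2 or siSMRT_E2_24h replicate 2 or 3 (adjusted p 0.056 to 0.1). That of IGFBP4 was lost without siCtrl_Veh_24h replicate 1 or 2, siCtrl_E2_24h replicate 1 or 3, siSMRT_Veh_24h replicate 2 or 3 or siSMRT_E2_24h replicate 1 or 2 (0.056 to 0.18). PREX1 lies outside the rule for naming genes and was named after its value was seen.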

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

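The tests of exchanged labels, of the separate normalization, of a true fall, of an innate response to siRNA, of signal near the floor and of splits that keep pairs of arrays together were chosen only after the result was seen; those of 1 aberrant array, of scaling and of the remaining splits of the samples were not.

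The E2 effect in control cells differed between 4 h and 24 h for 4097 genes, and estrogen-induced genes were lower in the arrays labelled E2 at 24 h. A shift common to 1 time cannot account for the fall at 24 h, which lies between arrays of that time. The list's median in siCtrl at 24 h was −0.93 after quantile normalization of all arrays together. For the same reason that step could hardly move it, so the value adds little. Correlated with the 4 h E2 effect, 12 of the 12 arrays of 24 h fell on the side of the other treatment, which exchanged labels and a true reversal would both give. The siCtrl mean of the estrogen-induced list was 8.57 in labelled E2 at 24 h and 8.68 in vehicle at 4 h. It was 9.76 in labelled vehicle at 24 h and 9.65 in E2 at 4 h. In siSMRT the same pairs were 8.87 and 8.89, and 9.79 and 9.77. Exchanged labels would give such levels directly, whereas a true fall needs the vehicle cells to rise with time as well. After quantile normalization of all arrays the siCtrl arrays labelled vehicle held the list 0.88 higher at 24 h than at 4 h (0.89 before). That argues against the scaling of the 2 times as the whole cause of this rise. Time in culture could also raise it, so exchanged labels and a true fall cannot be fully told apart. No array was relabelled.

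Interferon-stimulated genes were higher with siSMRT in the 4 comparisons by camera, a call lost with an estimated correlation in each (adjusted p = 0.232, 0.184, 0.0605 and 0.11 for vehicle and E2 at 4 h and labelled vehicle and E2 at 24 h). A single aberrant array does not account for it, as the lowest median over left-out arrays and comparisons was 0.48, in E2 at 4 h without siCtrl_E2_4h replicate 2. An innate response to the siRNA duplexes may contribute and cannot be told apart from an effect of SMRT, since 1 control and 1 SMRT-directed treatment were compared. The NF-kappaB list, which such a response could also raise, had a median of 0.03 averaged over the 4 comparisons, with members going both ways. An effect of SMRT on these genes was not tested.

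Replication and mitosis genes were lower with siSMRT in the 4 comparisons by camera, and by more in the arrays labelled E2 than in those labelled vehicle at 24 h (median differences −0.46 and −0.53). With an estimated correlation these calls were lost: adjusted p = 0.0908 for both lists in vehicle and 0.135 in E2 at 4 h, 0.468 and 0.431 in labelled vehicle and 0.0732 for both in labelled E2 at 24 h, and 0.067 and 0.103 for the difference. For that difference at 24 h, the highest median of the 83 genes over left-out arrays was −0.45. Over quantile normalization and median centring the higher of the 2 was −0.48. The value over left-out arrays argues against 1 array as the whole cause of the difference. Array medians at 24 h lay between 6.19 and 6.28, so the 2 scalings could hardly move a difference of this size. The value under them therefore adds little. The value over left-out arrays is for the difference alone. In the 4 siSMRT comparisons the medians of the 83 genes ranged from −0.74 to −0.22 under these 2 scalings. Signal near the floor would make the fall with siSMRT smaller where siCtrl is lower. The siCtrl arrays labelled E2 were lower than those labelled vehicle (median difference −0.37), yet the fall with siSMRT was larger there. The mean levels of the 83 genes had their median at the 81st percentile of all genes. Both argue against signal near the floor. A slower cell cycle after siSMRT may underlie the pattern, a hypothesis that no value here tests, nor was an off-target effect of the siRNA tested, and the dependence on E2 would change direction if the 24 h labels were exchanged.

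The difference of the E2 effect between siRNAs at 24 h passed for GJA1 (1.09), SDK2 (1.06), SYTL5 (1.00), RAPGEFL1 (0.96), JAK2 (0.95), IGFBP4 (0.93), PREX1 (0.67) and KCNJ13 (−1.51). In that difference the estrogen-induced list had a median of 0.26 (camera adjusted p = 1.56e-10, adjusted p = 0.067 with an estimated correlation). The estrogen-repressed list had one of −0.07, or −0.11 without siCtrl_Veh_24h replicate 1 and −0.12 without siSMRT_Veh_24h replicate 2 (camera adjusted p = 0.00195, 0.0549 without siSMRT_Veh_24h replicate 3; adjusted p = 0.249 with an estimated correlation). At 4 h the DNA replication list had a median difference of 0.11 (camera adjusted p = 0.000309), lost without siSMRT_Veh_4h replicate 1 or siSMRT_E2_4h replicate 3 (up to 0.699) and with an estimated correlation (adjusted p = 0.931). That median was 0.04 and 0.24 without siSMRT_Veh_4h replicate 1 and 3, and 0.17, 0.17 and 0.01 without siSMRT_E2_4h replicate 1, 2 and 3. The siSMRT effect was also compared between vehicle at 4 h and labelled vehicle at 24 h. If the 24 h labels were exchanged, this sets vehicle against E2. The arrays labelled vehicle at 24 h enter this comparison and E2 by siRNA at 24 h with opposite sign. Calls shared by the 2 are therefore not separate results. The siSMRT effect differed between these times for ST8SIA4 (0.69), GJA1 (−0.95), SDK2 (−1.04) and PREX1 (−0.65). The lists that passed there were estrogen-induced (−0.20, or −0.08 without siSMRT_Veh_4h replicate 2; camera adjusted p = 0.00492, 0.136 without that array), estrogen-repressed (0.19), DNA replication (0.33, or 0.21 without siSMRT_Veh_4h replicate 1), mitosis (0.34, or 0.21 and 0.52 without siSMRT_Veh_4h replicate 1 and 3), interferon-stimulated genes (0.46, or 0.30 without siCtrl_Veh_24h replicate 2) and cholesterol synthesis (0.13). With an estimated correlation none of these 6 passed (adjusted p = 0.501 for estrogen-induced, 0.445 for mitosis, 0.504 for interferon-stimulated genes and 0.331 for the others). Of 12083 clusters not listed in the annotation, which are outside the genes of the report, 257 passed the siSMRT test in vehicle at 4 h, 296 in labelled vehicle at 24 h, 124 in E2 at 4 h and 285 in labelled E2 at 24 h, adjusted over all clusters. Of the 18417 genes 1814, 1812, 1205 and 2251 passed.

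The counts were set beside those of other splits of the same arrays. For the 9 comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of them, gave 1362, 3270, 1814, 1812, 1205, 2251, 1149 and 2977 genes for the 8 comparisons within a time and 9805 for time, and the highest other split 0, or 1 for E2 in siSMRT at 24 h. Every other split mixes arrays of both real groups, which puts any real difference into the spread within groups. Low counts in those splits are therefore built in and do not measure chance. For E2 in siSMRT, where replicate numbers pair the arrays, the 4 splits that part all 3 pairs include the real one, and the others gave 0. For the 4097 genes of the E2 effect between times, 1 of 100 splits, the real one, gave as many and the highest other gave 3179. These splits exchange E2 and vehicle arrays within a time. They bear on an E2 effect at either time and cannot exclude chance for its difference between times. For the 4 genes of siSMRT by time 16 of 100 splits gave as many (highest other 3478). These splits can carry the siSMRT effect of 1 time into the difference, so they leave chance neither excluded nor shown. For the 8 genes of E2 by siRNA at 24 h, 11 of 100 splits gave as many (highest other 1577). These splits break the pairs of siSMRT arrays and can carry the siSMRT effect into the difference. Keeping vehicle and E2 arrays of a number together leaves 10 splits, too few for a share under 0.05. The real value was 8 and the highest other 0, or 177 and 1 with the pairs as a block. Without the block these splits put the siSMRT effect into the spread within groups, so a low count there is built in as well. For E2 by siRNA at 4 h the count is 0, so that 100 of 100 splits had to give as many and the splits say nothing about chance (highest other 1392). For each of these differences 4 to 6 of 100 splits gave over 500 genes, and the highest moved arrays of 1 side only. Moving 1 side carries the siSMRT or E2 effect itself into the difference. Such counts arise by construction and do not measure chance for the difference.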

How the results depend on the processing

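The fit on the 12 arrays of a time, the replicate block within siRNA and time, for genes and lists, and left-out arrays for the shared E2 response and the lists were chosen only after the result was seen. With all clusters, without dim genes, with quantile normalization, median centring, a trended and robust prior, a replicate block over all arrays or the arrays of a time, every count of genes stayed within 1.5 times. The array number and the signal over background limit how small a change can be called. Among calls of named genes, side and direction were kept by 772 with array weights (8 lost the call, 4 gained it and 1 turned), 726 with median centring and 753 with quantile normalization. KCNJ13 and SAMD9L are among the named genes that the filter on dim genes leaves out. Of 299 pairs of list and comparison, 98 passed camera; 18 of these were lost without at least 1 array, and 75 with an estimated correlation. For the changes below the cause was not tested, except that a fold minimum leaves fewer calls by construction. Using fewer arrays lowered some counts and raised others.

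With array weights the counts were 2136 for E2 in siCtrl 4 h, 2815 for siSMRT in vehicle 4 h, 2232 for siSMRT in E2 4 h, 37 for E2 by siRNA 24 h (14 higher, 23 lower, against 7 and 1) and 17 for siSMRT by time in vehicle (10 higher, 7 lower, against 1 and 3). With only the groups compared they were 941 and 1003 for siSMRT in vehicle 4 h and 24 h, 523 for siSMRT in E2 4 h, and 558 and 1647 for E2 in siSMRT 4 h and 24 h. For E2 by siRNA 24 h that fit, and the one on the 12 arrays of 24 h, which uses the same arrays, gave 4 higher and 5 lower against 7 and 1. RAPGEFL1 (adjusted p = 0.088), JAK2 (0.096) and IGFBP4 (0.08) then lost their calls. A minimum of 1.5-fold left 256 and 507 (E2 in siCtrl 4 h and 24 h), 298 and 316 (siSMRT in vehicle), 179 and 528 (siSMRT in E2), 228 and 599 (E2 in siSMRT), 1508 (E2 by time in siCtrl) and 1951 (time in siCtrl vehicle). A replicate block within time gave 18 for E2 by siRNA 24 h (10 higher, 8 lower), and one within siRNA and time 2117 for E2 in siCtrl 4 h, 1729 for E2 in siSMRT 4 h and 177 for E2 by siRNA 24 h (36 higher, 141 lower). The correlation of the E2 response between siRNAs was 0.75 at 4 h and 0.84 at 24 h without dim genes, and 0.39 and 0.69 by rank.

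Without 1 array the counts ranged from 839 to 1404 for E2 in siCtrl 4 h, 944 to 2104 for siSMRT in vehicle 4 h, 1086 to 2029 for siSMRT in vehicle 24 h, 564 to 1413 for siSMRT in E2 4 h, 6 to 19 for E2 by siRNA 24 h and 3 to 20 for siSMRT by time in vehicle. The differences that turned sign were near 0 and uncalled but for SQLE in time in siCtrl vehicle, at −0.07 with median centring. In E2 by siRNA 4 h they were ESR1 (−0.01, quantile normalization), CXCL12 (0.03, median centring) and TFF1 (−0.02, array weights). Over left-out arrays there, CXCL12 ranged from −0.15 to 0.20, ESR1 from −0.04 to 0.10, TFF1 from −0.06 to 0.17, GREB1 from −0.38 to 0.03 and CCND1 from −0.06 to 0.12. PGR turned to −0.02 in siSMRT in E2 4 h without siSMRT_E2_4h replicate 1 (highest 0.03) and to −0.12 in siSMRT in E2 24 h without siSMRT_E2_24h replicate 2 (highest 0.27), and ESR1 to −0.01 in siSMRT in vehicle 24 h without siSMRT_Veh_24h replicate 2 (highest 0.10).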

Other observations

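All values in this part were chosen only after the result was seen. In each of the 4 siSMRT comparisons 278 genes were higher and 263 lower, which covers more than the lists. ALCAM, a cell adhesion molecule, was higher by 1.19 and 1.56 at 4 h (vehicle, E2) and by 1.44 and 1.39 at 24 h (labelled vehicle, labelled E2), and CEACAM6, of the carcinoembryonic antigen family, by 0.94, 0.86, 1.46 and 1.55. EIF4G2, a translation initiation factor, was lower, at −0.83, −0.82, −0.82 and −0.85 in the same order. Among the clusters that the annotation does not list, 14 were higher and 42 lower in the 4 comparisons, cluster 7895087 at −1.33, −1.09, −1.23 and −1.13 and cluster 8095744 at 1.01, 1.04, 1.11 and 1.39.

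Within each of the 4 siSMRT groups, the array with the highest mean of the interferon-stimulated list had the lowest mean of the replication and mitosis genes. The siCtrl groups did not follow this throughout: the highest interferon mean was in replicate 3 with E2 at 4 h (9.12) and replicate 1 in the arrays labelled E2 at 24 h (9.25), and the lowest replication and mitosis mean in replicates 2 (8.95) and 3 (8.89). In vehicle at 4 h the pairs of means were 10.20 and 8.22, 9.82 and 8.42, and 9.46 and 8.75 for replicates 1, 2 and 3. In the arrays labelled E2 at 24 h they were 9.75 and 8.39, 10.33 and 8.17, and 10.60 and 8.14. Same-numbered siSMRT arrays of a time deviate together, so the 4 groups are not 4 independent cases.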
